A study of Caenorhabditis elegans with 2 samples.

How the data were processed

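The series profiled by ChIP-seq where ATTF-6, an AT-hook protein of the nematode Caenorhabditis elegans, sits on the genome of young adults aged 64 hours. Per the labels, the worms carried a CRISPR insertion that adds TY1, EGFP and FLAG tags to attf-6, were synchronised as starved first-stage larvae after bleaching, and were used whole. Chromatin was sheared by sonication to between 200 and 800 bp and precipitated with an antibody against GFP. The 2 samples form 1 group and are biological replicates 1 and 2 per the labels. No other group exists in the design, so the only comparison between samples is replicate 1 against replicate 2. The labels name a control experiment, which was not analysed here, so no region below was set against input or untagged chromatin. Per the deposited notes each list also derives from a further source file, whose content is not given in the sources used here.

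The data are 8 deposited peak lists on the ce11 assembly, per the deposited notes that accompany each sample. Every coordinate lay within the chromosome lengths of the reference, which is the same assembly under the name WBcel235. Each replicate has a ranked list and a thresholded list of its own, and both replicates together have 2 ranked and 2 thresholded lists, 1 of the latter named conservative. The aligner and the peak caller are not given in the sources used here. Total read counts per sample are not given either, so the sequencing depth is unknown and no interval below covers it. The signal of a region is the value the deposited lists give it, and it was used only to rank and describe regions within a list. The score in the deposited lists is a whole number that rises as the irreproducible discovery rate (IDR) falls. The deposited −log10 columns hold q values and the local and global IDR on that scale. Replicate signals for the joint ranked list stand in 2 columns with no replicate number, and 6 further columns with the replicates' region positions were not used.

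The thresholds behind the deposited lists were checked on the files. Every region of each thresholded list was found in its ranked list at a global IDR of 0.01 or less. Of 2267 ranked regions at that level, 2134 stand in the conservative list and 133 are missing from it. The role of the extra source file that the deposited notes name for thresholded lists is not given in the sources used here. The planned stricter setting of a global IDR of 0.01 was therefore the deposited threshold itself, and a level of 0.001 was added.

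All analyses used the summit of each region, counted from 1. The joint lists hold 35 intervals that are repeated with another summit, and each summit was counted. Gene models came from Ensembl release 115, with 19973 protein-coding genes on the 6 chromosomes. In that annotation 97 symbols are shared by 205 protein-coding genes. Such genes are named below by the RefSeq symbol of their WormBase identifier. A promoter was taken as 1000 bp upstream to 200 bp downstream of any annotated start of a protein-coding transcript. Shares of summits were compared with 10000 random placements of each summit on its own chromosome, with a two-sided permutation p. Replicate overlap was compared with 1000 placements, one-sided, and has Wilson intervals at 95%. Chromosome densities used exact two-sided binomial tests. The 29 gene lists were fixed before the data were examined and tested with two-sided Fisher exact tests against all other protein-coding genes, with Benjamini-Hochberg adjustment over the lists. The A+T content at summits was compared with the mean of the flanks centred 500 bp to either side by a sign-flip permutation test with 100000 draws. The k-mer test counted summit windows holding each 6-mer or its reverse complement against those flanks, with Fisher exact tests adjusted over 2080 6-mers. It pooled the flanks of all summits, so unlike the A+T test it did not pair each summit with its own flanks. All these tests treat summits or genes as independent, and their p-values describe the pooled lists, not the spread between animals. No p-value across samples is given, because an exact test on 2 replicates of 1 group cannot pass 0.05. Values from each replicate's own list are given beside the main pooled values, though not beside every gene list or class.

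Named genes followed a rule fixed before the data were examined. They are the 20 protein-coding genes with the nearest start at the strongest conservative summits that lie in a promoter and overlap a peak in both replicates' own lists, up to 4 members of each gene list with the strongest promoter summits, every attf gene, and the 5 strongest summits outside promoters. The piRNA-rich regions of chromosome IV were defined after the data were seen, as neighbouring 250 kb bins with at least 100 annotated piRNA genes. The gene families within the snRNA class, the split of bound genes by chromosome and the positions around piRNA starts were also chosen after the data were seen.

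The tests were tried on simulated data first. Random summits passed the 0.05 level in 4% of 100 runs of the placement test at tRNA genes, and in 100% of runs once 10% of the 2134 summits were moved to tRNA starts. Random promoter hits among 19973 genes gave any list past the threshold in 3% of 100 runs. Hits were drawn for each gene independently and summits evenly along each chromosome. These rates therefore do not cover neighbouring genes that share a summit or summits that cluster. A 6-mer planted in windows at 2134 random positions ranked 1 by p, and none passed without it. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives were the other joint list, the stronger part of the list, each replicate alone, other promoter and summit windows, other backgrounds, and settings added after the data were seen.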

Results

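ATTF-6 binding was mapped in 2 biological replicates of whole young adult worms carrying a GFP-tagged protein. The deposited lists hold 1219 regions for replicate 1 and 1110 for replicate 2, a ratio of 1.10. The joint conservative list holds 2134 regions and the other joint list 2269, of which 1786 are identical in both. Regions of the conservative list had a median width of 324 bp and a median signal of 80.8, as deposited. Coordinates are on ce11.

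The first question was whether the replicates marked the same places. Of the replicate 1 regions, 774 of 1219 overlapped a replicate 2 region by at least 1 bp, or 63.5% (95% Wilson interval 60.8 to 66.2). Of the replicate 2 regions, 753 of 1110 overlapped one of replicate 1, or 67.8% (65.0 to 70.5). Random placement gave 1.10% and 1.19%, and no placement reached the observed overlap (one-sided permutation p = 0.001 for each, the smallest that 1000 placements can give). In the other replicate's much longer ranked list, 97.2% of replicate 1 regions and 97.6% of replicate 2 regions had an overlap, against 26.2% and 26.9% for random placement (one-sided permutation p = 0.001 for each). Across the 79981 regions of the ranked joint list, the replicates' signals had a Spearman correlation of 0.28. Across the 2134 conservative regions it was 0.59. Those regions were selected by IDR, which favours regions ranked alike in both replicates. The higher value there is therefore not independent evidence of agreement. These correlations are across regions, which are not independent replicates. In the conservative list, 779 regions overlapped both replicates' own lists.

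The distribution over chromosomes was uneven. Chromosome IV held 1091 of the 2134 summits, or 51.1%, on 17.4% of the genome. Its density was 62.4 summits per Mb, against 15.1 on I, 13.1 on II, 13.0 on V and 7.73 on X, with 207 summits on III. The density on IV was 4.95 times that on the other chromosomes (exact binomial p = 2.25e-274). Replicate 1 alone had 615 of 1219 summits on IV and replicate 2 had 599 of 1110. The X chromosome was sparse, with a density 0.320 times that of the autosomes (exact two-sided binomial p = 1.55e-52). Replicate 1 gave 0.262 and replicate 2 gave 0.215. Without the right region of IV described next it was 0.508 (exact binomial p = 2.99e-16). The conservative counts leave out the 133 regions past the threshold that are missing from that list. Some of the strongest of them lie on X (signals 2673, 907 and 782) and others on IV and V.

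Most of the excess on IV lay in 1 stretch near its right end. Chromosome IV carries 14714 of the 15363 annotated piRNA genes, which encode the 21U-RNAs that guide the germline Argonaute PRG-1, most of them in 2 regions. The right region, from 13500001 to 17250000, held 798 summits, or 37.4% of all (35.4 to 39.5) on 3.74% of the genome. Its density was 212.8 summits per Mb, 15.4 times that of the rest of the genome. The left region, from 4750001 to 7000000, held 61 summits at 27.1 per Mb, and sequence outside both regions had 13.5 per Mb. Both replicates showed 426 summits in the right region. In the left region replicate 1 had 45 and replicate 2 had 41. Annotated piRNA genes number 11525 in the right region and 2814 in the left one. A summit lay within 500 bp of 21.9% of the former and of 0.426% of the latter. No share for random positions in the right region, where summits are dense, is given beside these. Over the whole genome, summits within 500 bp of piRNA starts were 0.947 times as many as for random positions within 50 kb.

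**Figure D1:**
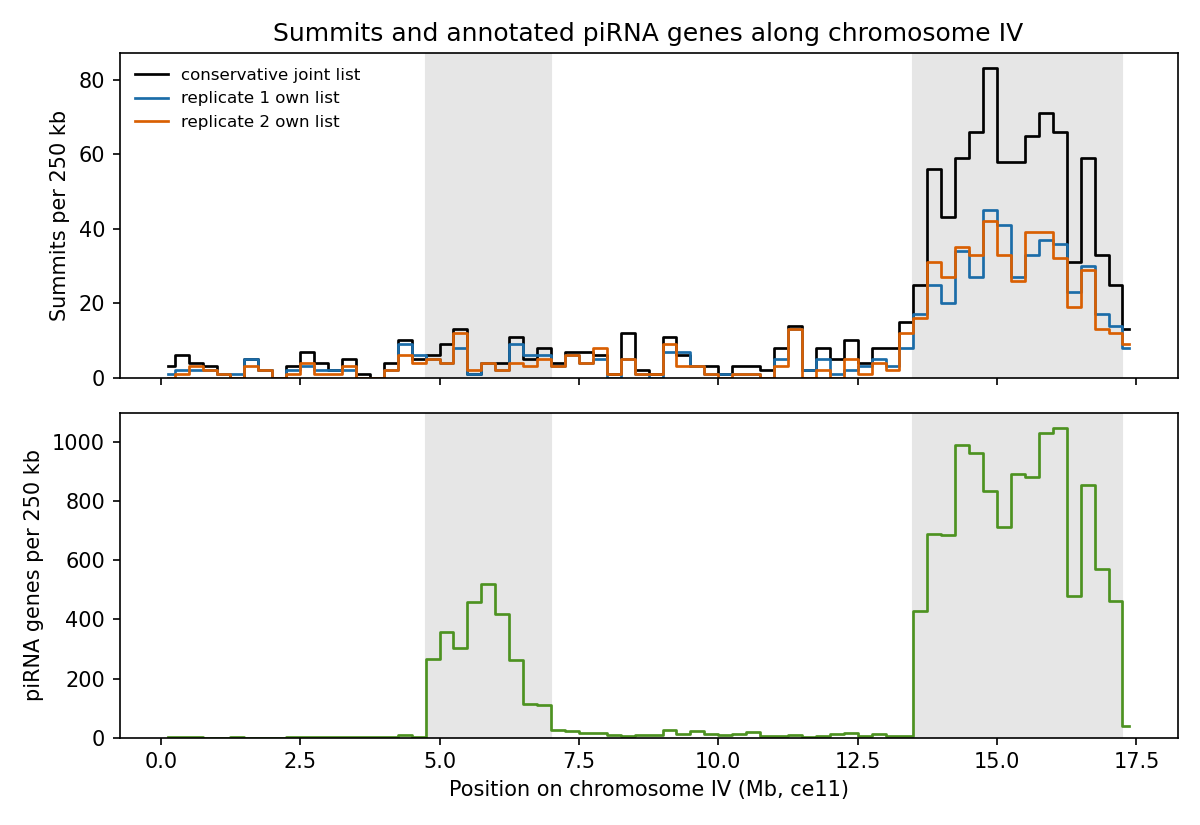
Summits per 250 kb (top, conservative list and each replicate's own list) and annotated piRNA genes per 250 kb (bottom) by position on chromosome IV in Mb; the grey bands are the piRNA-rich regions. The right band holds 798 conservative summits and the left band 61.

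Within the right region the summits were placed unevenly around piRNA genes. Sequence from 1 to 200 bp downstream of a piRNA start held 465 of the 798 summits, or 58.3%, against 37.1% for random positions in the region (1.57-fold, two-sided permutation p = 2e-04, the smallest that the placements can give). Replicate 1 had 196 of 426 there and replicate 2 had 208 of 426. The 200 bp upstream held 33.6% against 37.0% at random (permutation p = 0.0498). Without summits near tRNA, snRNA or snoRNA genes it was 34.7% (permutation p = 0.217). In the replicates' own lists the upstream share was 23.9% and 27.7% (permutation p = 2e-04 and p = 4e-04). The sequence CTGTTTCA is the core of the upstream motif of piRNA genes. It was found close to 25.7% of the summits and in 27.6% of equal windows 2000 bp away (two-sided Fisher exact p = 0.353). Nearly all of those windows lie in the same piRNA-rich region. The motif lies upstream of piRNA starts, whereas the summits gathered downstream of them. The comparison therefore cannot tell whether the summits are tied to the motif.

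**Figure D2:**
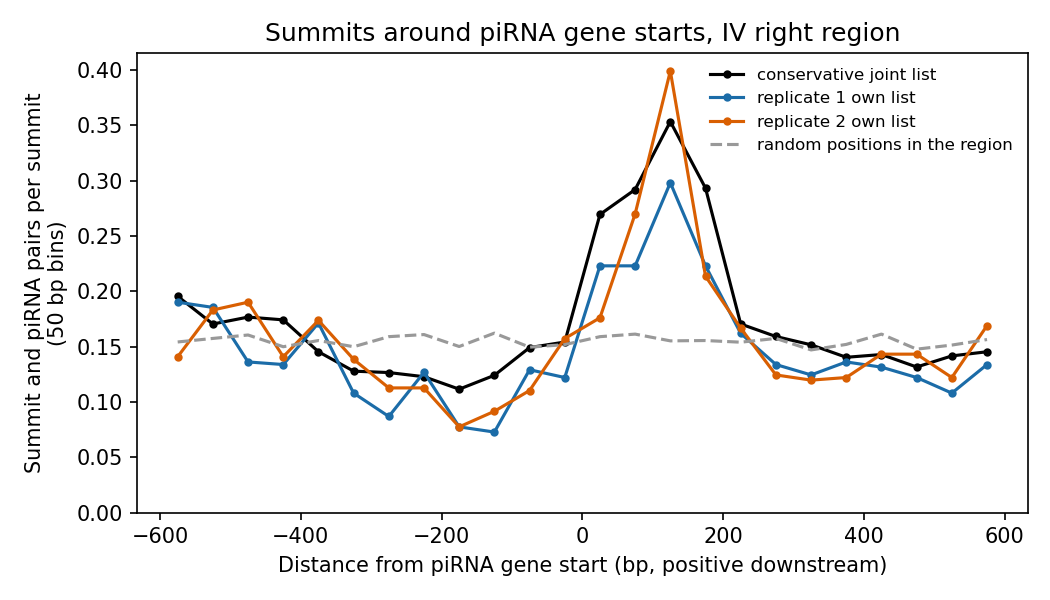
Summit and piRNA pairs per summit in 50 bp bins by distance in bp from piRNA gene starts in the right region of chromosome IV, for the conservative list, each replicate's own list and random positions in the region. The lines for the summits rise above the random line from 0 to 200 bp downstream.

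The central part of each chromosome, taken as equal in length to either outer part, had 0.633 times the density of the outer parts (exact binomial p = 8.39e-21). Chromosome IV set this value, at 0.263. Ratios were 1.08 on I, 1.15 on II, 1.31 on III and 1.27 on V, none past 0.05. Without the right region of IV the ratio was 1.18 (exact binomial p = 0.00403), which turns the direction.

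Genes for short structured RNAs were marked far above chance. Summits lay within 500 bp of a tRNA gene start in 210 cases, 22.4-fold over random placement. For snRNA genes there were 94 (26.8-fold) and for snoRNA genes 100 (13.7-fold). Each had a two-sided permutation p of 2e-04 (adjusted p = 0.00032 over 8 classes). Replicate 1 alone gave 24.4-fold, 41.5-fold and 18.3-fold for tRNA, snRNA and snoRNA genes. Replicate 2 gave 21.3-fold, 43.0-fold and 20.1-fold. Against random positions within 50 kb the tRNA fold was 12.8. Within 200 bp of a start, the tRNA, snRNA and snoRNA folds were 51.3, 51.9 and 27.3. Counted by gene, 241 of 612 tRNA genes had a summit within 500 bp, or 39.4% (35.6 to 43.3), as did 71 of 129 snRNA genes and 91 of 346 snoRNA genes. The share of tRNA genes was lower in the replicates' own lists, at 24.2% in replicate 1 and 18.3% in replicate 2. Together such genes lay near 399 summits, and near 53 of the 100 strongest.

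Among snRNA genes, those for the SL2 spliced leader, the short RNA that is trans-spliced onto downstream genes of operons, had a summit at 17 of 18, or 94.4% (74.2 to 99.0). Replicate 1 marked 17 of them and replicate 2 marked 16. The strongest summit of the list, at II 5844846 with a signal of 3469, lay 19 bp from the start of sls-2.1. The next, at I 4172188 with 2754, lay 18 bp from sls-2.4, and the third, at II 5543604 with 2290, lay 6 bp from sls-2.2. The smy genes, which encode RNAs tied to trans-splicing, had a summit at 8 of 10. None of the 12 SL1 genes had one. They lie in a repeat on chromosome V, where 9 regions past the threshold in the ranked list are missing from the conservative list. Among ribosomal RNA genes 1 of 20 had a summit.

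The remaining classes were less marked. Summits near annotated ncRNA genes numbered 310 (2.75-fold) and those near miRNA genes 13 (2.53-fold, adjusted permutation p = 0.00667). The miRNA call was lost with replicate 2 alone, at 1.87-fold (permutation p = 0.269), and at an IDR of 0.001, with 5 summits near miRNA genes (permutation p = 0.192). Near piRNA genes there were 615 summits (2.27-fold, adjusted permutation p = 0.00032). This came from the right region of IV, since without it the fold was 0.820 (permutation p = 0.262). Against random positions within 50 kb it was 0.947 (permutation p = 0.0068). For lincRNA genes there were 3 summits (0.805-fold, adjusted permutation p = 0.975).

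**Figure D3:**
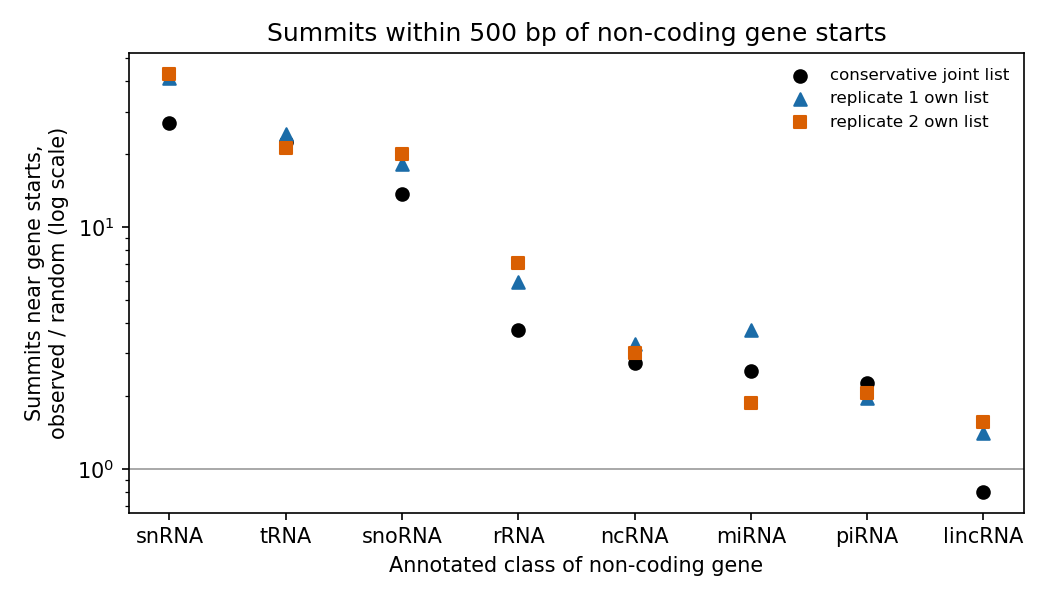
Summits within 500 bp of non-coding gene starts, as observed over randomly placed summits on a log axis, by annotated class; points are the conservative list and each replicate's own list. The snRNA, tRNA and snoRNA classes stand at 26.8, 22.4 and 13.7 in the conservative list.

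The share of marked genes differed by place for some classes. In the right region of IV, 32 of 32 tRNA genes had a summit within 500 bp, against 94 of 304 on the other autosomal sequence (two-sided Fisher exact, adjusted p = 3.84e-15). On X it was 115 of 276, or 41.7%, with an odds ratio of 1.60 against that other autosomal sequence (adjusted Fisher p = 0.0148). This comparison leaves out the 32 marked genes of the right region, which would raise the autosomal share. Of 33 snoRNA genes on X, 3 had a summit (odds ratio 0.267, adjusted Fisher p = 0.0336), and of 8 in the right region 5 did (adjusted Fisher p = 0.0565). The snRNA genes did not pass in either place, with 6 of 8 in the right region (adjusted Fisher p = 0.464) and 0 of 3 on X (adjusted Fisher p = 0.11). Protein-coding genes on X were marked less often too. There 31 of 2731 had a promoter summit, or 1.14%, against 698 of 16778, or 4.16%, on other autosomal sequence (odds ratio 0.265, adjusted Fisher p = 6.55e-18). In the right region 127 of 464 did, or 27.4% (odds ratio 8.68, adjusted Fisher p = 6.13e-61). Summits there are 15.4 times as dense as in the rest of the genome, so any position lies near one more often. The right-region comparisons, that of tRNA genes included, do not separate marking of genes from this density. Inside the region, promoters held 21.8% of summits against 18.2% at random. Of the 137 summits on X, 95 lay within 500 bp of a tRNA gene start.

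Promoters of protein-coding genes held 799 of the 2134 summits, or 37.4% (35.4 to 39.5), against 26.3% at random (1.43-fold, two-sided permutation p = 2e-04). Each replicate's own list gave 40.5%. On the autosomes outside the right region the share was 49.6%, 1.80-fold over chance. In the right region it was 21.8% against 18.2% at random there (permutation p = 0.0084), and on X 21.9% against 21.8%. Exons held 12.1% of summits (0.583-fold) and introns 16.7% (0.621-fold), each with a permutation p = 2e-04. Sequence within 1000 bp past a gene end held 12.1% (2.12-fold, permutation p = 2e-04), and other intergenic sequence 21.6% (1.06-fold, p = 0.147). The intergenic value was set by the right region, without which it was 0.579-fold (permutation p = 2e-04). The signed distance to the nearest transcript start had a median of 29 bp and quartiles at -559 and 1470 bp. Summits lay to both sides, since the median distance without sign was 1046.5 bp and 16.9% lay within 200 bp. The signed median was -37 bp in replicate 1 alone, -46 bp among stronger summits, -31 bp at an IDR of 0.001 and -10 bp without the right region.

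The strongest promoter summits found in both replicates belonged mostly to chromosome IV, which held 16 of the 20 named genes. All 16 of these summits lie in the piRNA-rich right region, where promoters held 21.8% of summits against 18.2% at random. In 9 of the 20 a gene for a tRNA, snRNA, snoRNA or rRNA started within 500 bp of the summit. The summit 599 bp upstream of egg-5, an oocyte protein of the egg-to-embryo transition, is the one at sls-2.4. That 769 bp upstream of the F-box gene fbxa-83 had a signal of 2136 at IV 14327152 and lay 31 bp from a snoRNA gene start. Others had no such gene nearby. The promoter of ntl-11, a CCR4-NOT deadenylase subunit, had a summit at IV 15471613 with a signal of 777, 118 bp upstream of the start. That of dld-1, the dihydrolipoyl dehydrogenase, had 666 at IV 14464263, and that of thoc-7, of the THO mRNA export complex, had 629 at IV 13882754. The summit 264 bp upstream of rpl-29 had 505. The remaining named genes were H41C03.3, pkd-2, Y7A9D.1, Y75B8A.23, Y57G11C.5, Y45F10B.59, eelo-2, C33B4.4, Y41E3.1, Y73F8A.27, Y40H7A.4, Y65A5A.2, ari-1.4 and Y43D4A.5, with signals from 454 to 3469. Among them, the summit of H41C03.3 is the one at sls-2.1. Those of pkd-2, Y7A9D.1, Y75B8A.23, Y57G11C.5, Y45F10B.59 and Y43D4A.5 also lay within 500 bp of a tRNA or snRNA gene start.

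Outside promoters the strongest summit was that at sls-2.2. The next, at IV 14525749 with a signal of 1902, lay 312 bp from the piRNA gene 21ur-15698 and 552 bp from srh-63. The summit at IV 15234428 (1298) lay in an intron of pkd-2, a polycystin of male sensory neurons, 18 bp from a snoRNA gene start. That at IV 14764888 (1064) lay in an intron of Y57G11C.5, 146 bp from an snRNA gene start, and that at IV 15693461 (1019) in an intron of Y105C5A.15.

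Promoter summits were found at 856 of 19973 protein-coding genes, or 4.29%. Of the 29 gene lists, 9 held more of them than other genes and 3 fewer by the Fisher exact test with Benjamini-Hochberg adjustment. Ribosomal protein genes led, with 22 of 80 or 27.5% (odds ratio 8.67, adjusted Fisher p = 2.28e-11). Replicate 1 marked 22.5% of them and replicate 2 marked 16.2%. Without summits near tRNA, snRNA or snoRNA genes it was 21 of 80. The strongest were at rpl-29, rpl-20 (signal 298), rpl-3 (264) and rpl-15 (231). Mitochondrial respiratory chain genes had 11 of 46 (odds ratio 7.10, adjusted Fisher p = 2.28e-05), among them cyc-2.1 (144), cox-5A (122), cox-6A and cox-5B (94.4). Replicate 1 alone had 6 of 46 and replicate 2 had 5. At an IDR of 0.001 it was 4 of 46 and the call was lost (odds ratio 4.12, adjusted Fisher p = 0.0735).

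Genes of the germline and of dividing cells were marked too. Of 38 germline and oocyte genes 10 had a promoter summit (odds ratio 8.06, adjusted Fisher p = 2.28e-05), led by cpg-1, an eggshell proteoglycan (215), mex-5, a polarity protein (137), rme-2, the yolk receptor (137), and mex-1 (117). Meiosis genes had 7 of 27 (odds ratio 7.87, adjusted Fisher p = 4.49e-04). They were led by syp-4 of the synaptonemal complex (189), the cohesin rec-8 (137), msh-5 and coh-3 (100.3). The syp-4 summit lies in an snRNA gene, and without summits near short RNA genes the count was 6 of 27 (odds ratio 7.51, adjusted Fisher p = 0.00137). The summit between mex-5 and rec-8 is shared. Of 44 cell cycle and DNA replication genes 9 were marked (odds ratio 5.79, adjusted Fisher p = 4.15e-04), with the centromeric histone hcp-3 (226), the centriole protein sas-6 (172), hcp-4 (146) and mcm-2 (141) strongest. The chromatin list of SynMuv, DREAM and Polycomb-type genes had 5 of 35 (odds ratio 3.74, adjusted Fisher p = 0.0386), among them the E2F gene efl-1 (387), lin-54 (215), lin-53 (106) and lin-52 (75.3). The lin-54 summit lies 351 bp from lin-54 but 42 bp from the ribosomal protein gene rpl-12. That of lin-53 is as near to nra-2, at 233 bp, as to lin-53, at 234 bp. The call of the chromatin list was lost among stronger summits, with a similar odds ratio of 3.62 (adjusted Fisher p = 0.153). It was also lost at an IDR of 0.001 (odds ratio 4.05) and on a background without chemoreceptor and F-box genes (3.48). With promoters of 2000 bp and with the nearest start only, it was lost at lower odds ratios of 2.45 and 2.77.

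Chaperone genes had 10 of 61 (odds ratio 4.42, adjusted Fisher p = 8.91e-04), with cct-8 (220), hsp-1 (212), hsp-60 (161) and dnj-13 (140) leading. The dnj-13 summit lies inside dhgd-1. Those of hsp-60 and cct-8 lie nearer to Y22D7AL.10 (182 bp) and Y55F3AR.2 (181 bp). Assigning each summit to its nearest transcript start ended the call of the chaperone list (adjusted Fisher p = 0.29). Translation factor genes had 7 of 40 (odds ratio 4.77, adjusted Fisher p = 0.00406), such as eif-2Bgamma (249), eif-3.C (106), iff-2 (80.8) and eif-2D (73.0). The eif-2Bgamma summit lies in the snRNA gene sup-39 within C15F1.5, 761 bp upstream of eif-2Bgamma. Without summits near short RNA genes the count was 6 of 40 (odds ratio 4.64, adjusted Fisher p = 0.00943). In replicate 1 alone this odds ratio was 0.876 (adjusted Fisher p = 1). Histone genes had 13 of 72 (odds ratio 4.98, adjusted Fisher p = 5.93e-05), at his-42 (343), his-65 (149), his-46 (138) and his-56 (136). These summits lay 602 to 826 bp upstream. In replicate 2 alone 15 of 72 were marked, with an odds ratio of 10.4. With a promoter of 500 bp the odds ratio was 0.891, and with the nearest start only it was 0.841 (adjusted Fisher p = 1 for both).

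The lists with fewer promoter summits were chemoreceptor-like genes, with 14 of 1364 or 1.03% (odds ratio 0.219, adjusted Fisher p = 2.09e-11), nuclear hormone receptors, with 3 of 274 (odds ratio 0.245, adjusted Fisher p = 0.0106), and F-box genes, with 3 of 322 (odds ratio 0.207, adjusted Fisher p = 0.00243). The chemoreceptor-like genes with the strongest summits were srh-269 (186), srz-97 (144), sru-9 (130) and sre-23 (121). The hormone receptor genes were nhr-47, nhr-255 and nhr-142, and the F-box genes fbxa-83, fbxa-90 and fbxa-111. The summit of fbxa-90 is that of efl-1. The F-box call was lost in each replicate's own list, with adjusted Fisher p of 0.185 and 0.158 and odds ratios of 0.426 and 0.359. It was also lost among stronger summits (odds ratio 0.358, adjusted Fisher p = 0.172) and at an IDR of 0.001 (odds ratio 0.400, adjusted Fisher p = 0.31). The hormone receptor call was lost in replicate 1 alone, with a similar odds ratio of 0.249 (adjusted Fisher p = 0.0708). It was also lost among stronger summits, at an IDR of 0.001 and without the right region of IV (adjusted Fisher p of 0.15, 0.261 and 0.051), where the odds ratios were 0.280, 0.313 and 0.290.

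Among the genes named for the lists, the summits of his-42, syp-4, unc-31, nhr-255, cox-6A, pas-5, eif-2Bgamma, snr-4, srh-269, srz-97, sre-23 and fbxa-83 lay within 500 bp of the start of a tRNA, snRNA or snoRNA gene. Those of eif-2D, col-133, unc-25, nhr-142, rpn-10, nhl-2 and mig-5 had no region in either replicate's own list. Those of eif-3.C, iff-2 and lin-52 had one in replicate 2 only, and those of msh-5, nhr-255, rpn-3, uaf-2 and sre-23 in replicate 1 only. Another protein-coding gene lay nearer to the summits of rpl-20, his-65, his-46, his-56, col-63, mex-5, msh-5, nhr-142, cox-6A, pas-5 and eif-2Bgamma. The same held for eif-3.C, eif-2D, snr-1, prp-19, uaf-2, cct-8, hsp-60, dnj-13, nhl-2, mig-5, srh-269, lin-54, lin-53 and fbxa-90.

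The other 17 lists did not pass. Splicing genes did pass in each replicate's own list (Fisher exact adjusted p = 0.00364 in replicate 1 and p = 0.0432 in replicate 2). In the conservative list they had 1 of 40 with the nearest start only (odds ratio 0.755). Without the right region of IV they had 2 of 40 (odds ratio 1.39, adjusted Fisher p = 0.866). In the other joint list splicing, proteasome and heterochronic genes passed with more summits and homeobox genes with fewer (adjusted Fisher p of 0.0233, 0.0378, 0.0413 and 0.0424), and 12 lists in all had more. Splicing and homeobox genes also passed with promoters of 2000 bp (adjusted Fisher p of 0.0297 and 0.0121) and collagens with those of 500 bp (0.02). Summits were found at 4 of 40 splicing genes (snr-4, snr-1, prp-19 and uaf-2, adjusted Fisher p = 0.176), 3 of 33 proteasome genes (pas-5, rpn-3 and rpn-10, adjusted Fisher p = 0.302), 2 of 39 neuronal genes (unc-31 and unc-25), 2 of 175 cuticle collagens (col-63 and col-133, adjusted Fisher p = 0.0761), 1 of 13 heterochronic genes (nhl-2) and 1 of 24 Wnt pathway genes (mig-5). The 11 lists with no promoter summit were the homeobox genes (0 of 95, adjusted Fisher p = 0.0761), muscle, major sperm protein, intestine, hypodermis and seam, Notch and EGF/Ras, insulin and stress, pharynx, dosage compensation, vitellogenin and AT-hook genes. The attf-6 gene itself (WBGene00012474, I 12787943 to 12806581) had no promoter summit, and its nearest summit lay 33.7 kb from its start. The nearest summits to attf-2, attf-3, attf-4 and attf-5 lay 2.39, 2.99, 78.7 and 298.5 kb away.

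**Figure D4:**
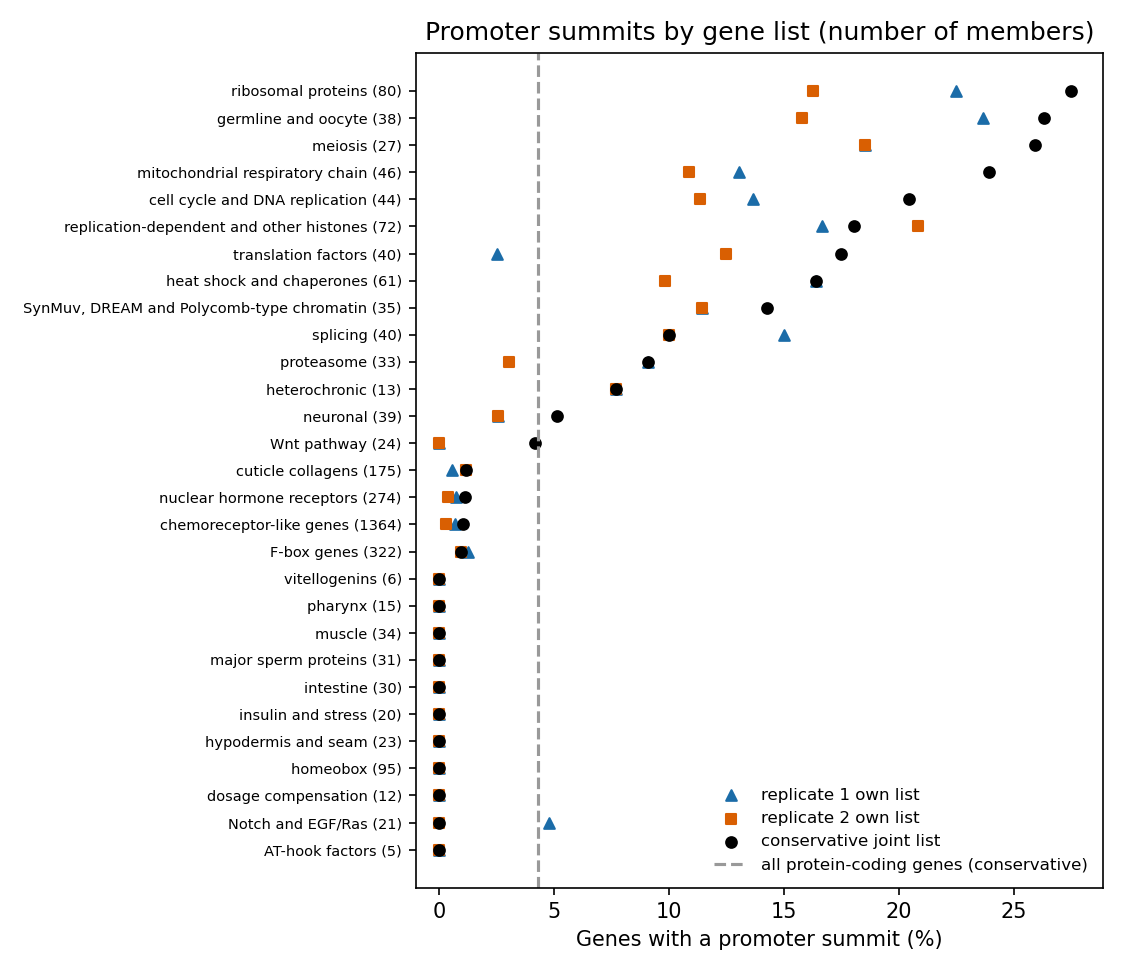
Percentage of the members of each gene list with a promoter summit, for the conservative list and each replicate's own list; the dashed line marks all protein-coding genes at 4.29%. Ribosomal protein genes stand at 27.5% and chemoreceptor-like genes at 1.03%.

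The sequence at summits was poorer in A+T than its surroundings. The window centred on the summit was 57.8% A+T and its flanks 64.0%, a difference of -6.22 percentage points (SE 0.247 over 2134 summits, sign-flip permutation p = 1e-05, the smallest that 100000 draws can give). It was lower at the summit in 67.7% of cases. Replicate 1 gave -6.96 and replicate 2 gave -6.48. Summits near tRNA, snRNA or snoRNA genes differed by -12.2 points, those elsewhere in the right region of IV by -4.37 and the others by -5.21. Promoter summits were 55.3% A+T, against 64.8% at random promoter positions (permutation p = 1e-05).

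Of 2080 6-mers, 498 were more frequent at summits than in the flanks and 277 less frequent at an adjusted p under 0.05. The 10 with the highest odds ratios among those in at least 5% of summits were CGCGCG (odds ratio 6.63), ACGCGC (5.89), GCGCGC (5.65), CGCGCC (5.55), CGCGGC (5.09), CCGCGC (4.78), CACGCG (4.77), GCGCAC (4.76), CGCGCA (4.71) and GAACCC (4.63). Each stands for itself and its reverse complement. The flanks were not matched to the summits in A+T content. The counts and the G+C-rich 6-mers may therefore restate the lower A+T content above rather than mark a binding motif. CGCGCG was in 5.25% of summit windows and 0.820% of flanks (adjusted Fisher p = 2.51e-24). GAACCC, whose reverse complement GGGTTC is part of the internal B box of tRNA promoters, was in 8.25% and 1.90% (adjusted Fisher p = 9.72e-29). In the replicates' own lists the odds ratio of CGCGCG was 16.1 and 7.06, and that of GAACCC was 5.09 and 4.75. Among the 6-mers with the lowest odds ratios were CATAAA (0.544) and TAAAAA (0.568).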

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

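Regions that passed the threshold in the ranked joint list but are missing from the conservative list were looked at because no comparison above uses them. There are 133 of them, and the strongest has a signal of 2673. It lies on X from 15810944 to 15811209, with a pseudogene 857 bp away as the nearest annotated gene. The strongest of 9 missing regions in the repeat of 5S ribosomal RNA and SL1 genes on chromosome V, from 17122891 to 17123190, has a signal of 1875. The missing regions include signals near the top of the list, where the maximum kept is 3469. Whether their absence accounts for the lack of summits at SL1 genes, or for the low count at ribosomal RNA genes, was not tested. No control chromatin was analysed here, so the level of these regions without the tagged protein is not given.

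All tests of the next 3 patterns except that of the weaker regions' A+T content were chosen after the results were seen. The first pattern is the density of summits in the right piRNA-rich region of chromosome IV. It does not follow the number of annotated piRNA genes alone, since summits per piRNA gene were 3.19 times as many in the right region as in the left (exact 95% interval 2.46 to 4.22). Sequence elsewhere with the same A+T content held 6.69 summits per Mb (SE 0.548), against 211 in matching bins of the region (SE 12.6). A gain in copy number or background over the whole region stays open, since ranked regions with a signal below the median were 1.40 times denser there (1.34 to 1.46), against 15.4 times for the thresholded summits, but such a gain would itself lift regions above that median. Open chromatin or transcription specific to the region was not tested, and neither was a biological explanation.

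The second pattern is the marking of tRNA genes, for which a single test of repeated copies was split in 2 after its outcome was seen. Reads shared between identical copies cannot be the whole cause. Reads shared between copies that are similar but not identical were not tested, and the aligner is not known. Of 110 single-copy tRNA genes with no repeated one within 1 kb, 27.3% had a summit within 500 bp (19.8 to 36.3), against 0.909% of positions 10 kb away (0.250 to 3.25). Shared reads may still add to it, because repeated tRNA genes had a summit 1.45 times as often as single-copy ones (42.4% against 29.3%, two-sided Fisher exact p = 0.00577). Highly transcribed genes can draw signal in ChIP whatever the antibody, and with no control analysed here this stays open.

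The third pattern is the lower A+T content at summits of a protein named for an AT-hook. It is not owed to tRNA, snRNA and snoRNA genes alone, since without summits near them the difference was -4.85 points (SE 0.267). A bias of sequencing or shearing toward G+C stays open. Ranked regions with a signal below the median differed by -2.07 points, 0.333 times the difference at the thresholded summits (0.303 to 0.363), and the bound set in advance to exclude this explanation falls inside that interval.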

How the results depend on the processing

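Among alternatives for single lists, classes and features, 389 stayed on the same side of the threshold, 19 lost their call, 9 gained one and 5 turned direction with a call in at least one of the pair compared. Some that passed in neither setting turned too, such as the lincRNA fold, at 1.60 among stronger summits. For the results that answer a comparison, 3 turned direction. The region of IV, the settings without it, placement within 50 kb, the IDR of 0.001 and the removal of summits near short RNA genes were chosen after the data were seen. Each cause below was not tested unless said. The signal correlation was 0.586 over conservative regions, which the IDR selects for replicate agreement, and 0.426 over the 5000 strongest. Without the right region of IV, which holds 37.4% of summits, the ratio of central to outer parts of chromosomes was 1.18, the X to autosome density 0.508, the piRNA fold 0.820, the snRNA fold 46.3 and the intergenic fold 0.579. Within 50 kb the piRNA fold was 0.947 and the tRNA fold 12.8. Within 200 bp of starts the tRNA, snRNA and snoRNA folds were 51.3, 51.9 and 27.3. At an IDR of 0.001 the snRNA and snoRNA folds were 52.1 and 23.1, and among stronger summits the snRNA fold was 42.4 and the snoRNA fold also over 1.5 times higher. With either replicate alone the snRNA fold was 41.5 to 43.0. With promoters of all genes the intergenic fold was 0.313 and the intron fold 0.181, and 1654 summits then counted as in a promoter. The exon fold was 0.387 among stronger summits. Lists with fewer summits numbered 1 in the stronger part of the list, at an IDR of 0.001 and on a background without chemoreceptor and F-box genes, which leaves 2 of them out, and 1 to 2 with either replicate alone. The odds ratio of histones was 0.891 with promoters of 500 bp and 0.841 with the nearest start, 7.86 among stronger summits, 7.92 at an IDR of 0.001 and 6.96 to 10.4 with either replicate alone. That of translation factors ranged from 0.876 to 5.56 with either replicate alone, and its call was lost among stronger summits (3.13) and at an IDR of 0.001 (2.27). With either replicate alone the odds ratio ranged from 0.107 to 0.214 for chemoreceptor-like genes and from 4.25 to 6.80 for chaperones. As 8-mers, 769 were more frequent and 127 less frequent, of a larger set. Less frequent 6-mers numbered 149 to 228 with either replicate alone. The median distance to a start was -46 bp among stronger summits, -31 bp at an IDR of 0.001, -10 bp without the right region, and -37 to 15 bp with either replicate alone. Sequencing depth is unknown.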

Other observations

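The share of summits near tRNA, snRNA or snoRNA genes followed signal. It was 32.6% among the 533 strongest summits of the conservative list, 18.5% and 14.4% in the next ranks and 9.18% among the 534 weakest. The promoter share went from 42.8% to 33.9% over the same ranks. The share in the right region of chromosome IV was 36.6% among the strongest and 41.2% among the weakest. Outside chromosome IV, 10 of 649 piRNA genes had a summit within 500 bp.

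The pooling of lists below was chosen after the result of each list was seen, so its p-values describe lists already known to differ and do not test germline use. Genes of the germline, meiosis and cell cycle lists had a promoter summit in 26 of 109 cases, or 23.9%. Those of the neuronal, muscle, intestine, hypodermis, pharynx and homeobox lists had one in 2 of 226, or 0.885% (odds ratio 35.1, two-sided Fisher exact p = 4.59e-12). On the autosomes alone the odds ratio was 25.2 (Fisher exact p = 1.09e-09). The major sperm protein genes, also used in the germline, were in neither pool and had 0 of 31. The lists were written by hand and hold few genes, tissues were not separated, and strongly transcribed genes such as those for ribosomal proteins were marked as well, so transcription level and germline use were not told apart.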
